A study of Ovis aries with 15 samples.

How the data were processed

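Liver of fetal sheep (Ovis aries) was sampled at gestational days (GD) 100, 124 and 144, and 15 libraries were sequenced, 4, 5 and 6 from these stages. The intervals between the stages were 24 and 20 days. Per the labels' protocols, the libraries were paired-end libraries made after poly(A) selection from total RNA of the tissue. The deposited table gives an estimated count of reads for each of 31411 genes in each library, and its values are not normalised. DRAGEN, a read mapping and counting platform, is named in the submitters' processing notes, while its version, the genome build, the annotation and whether counting used the strand are not given in the sources used here. Of all values 6.549% were fractional, and values were rounded to whole numbers, which changed no library total by more than 27.86 reads. No line of the table lacked a gene name, and each of its 15 columns belonged to 1 library.

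Gene names were used as the table gives them. In the RefSeq table of assembly ARS-UI_Ramb_v3.0, 28863 names matched a symbol and 13 matched a locus tag alone. A further 2535 matched neither, 2373 of them names that begin with TRNA. That table also served to find genes that overlap another gene. Whether the table was counted on this assembly is not known, so only names and overlaps were taken from it.

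Library totals ran from 24215612 to 38247295 counts. A floor of detection was set at 3 counts, which is 0.0784 to 0.124 counts-per-million units (CPM), and such floors cover counting error only. CPM values use factors from the trimmed mean of M values (TMM), except the sums over Y-linked genes and the search for genes high in GD100 replicates 2 to 4, which use total counts alone. Pairs of replicates were checked for duplicated data over genes with at least 20 counts. The lowest chi-square per degree of freedom was 43.72, far from that of 1 sample sequenced again.

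Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM factors, robust estimation and 1 fit of all 15 libraries with a term per stage. The filterByExpr function left 16977 genes. The common dispersion was 0.1156, a biological coefficient of variation of 34%, with a median of 4.44 prior degrees of freedom. GD124 was compared with GD100, GD144 with GD124 and GD144 with GD100, and further tests asked for any difference between stages and for a difference between the changes of both intervals. P-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. Each standard error of a log2 fold change was taken as the size of the change divided by the square root of its F value. Because both intervals share the GD124 libraries, overlaps between them were set beside 20 simulated tables without a stage effect and beside independent lists.

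A set of 37 gene lists was written for functions of the liver and for cells that a piece of liver can hold. Each list was tested in each pairwise comparison with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over all 111 tests. Beside it stand camera with an estimated correlation, the fry test, and counts of members called over all genes and adjusted over the list alone. Principal components were computed from log2 CPM with a prior count of 2 over the 500 genes of largest variance. The distance between and within stages was compared by a permutation test of 100000 draws.

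The genes named follow a rule. In each pairwise comparison these are the 8 largest rises and the 8 largest falls among called genes that have a symbol, a mean of at least 10 CPM in the higher stage and no overlap between the libraries of both stages. To these come 25 genes fixed in advance, of which 23 were tested, and up to 4 further members of each list described. H19, CYP7A1 and XIST are not analysed here, and a few other genes that the rule names are not reported here. VTN, ORM1 and LOC121818276 were picked after their values were seen. The comparisons, tests, lists and naming rule, and the alternatives except those described as added later, were set before the data were examined.

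The edgeR procedure was tested on simulated data with known fold changes. They used the library sizes of this table and the mean of each gene over all libraries. For GD124 against GD100, over 16629 genes, 7.6, 39.4 and 78.3% of genes changed 1.5-, 2- and 4-fold were found, and 2.5% of calls were false. For GD144 against GD124, over 16640 genes, the shares were 13.8, 44.6 and 82.8%, with 4.2% of calls false. For GD144 against GD100, over 16653 genes, they were 7.6, 39.4 and 81.2%, with 3.5% false. Only 60 to 66 genes were changed at each fold, whereas the data gave 5774, 4663 and 9342 calls in these comparisons. The shares found and the shares of false calls depend on how many genes change, so they need not hold for the data.

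The alternatives were other scalings (RLE size factors, total counts alone, TMM without the 20 most abundant genes), no filter beyond a count above 0, a filter of 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, robust estimation switched off, the replicate number as a block, each library left out in turn, counts thinned to 24215612 per library, only the stages compared, and edgeR's glmTreat against a fold of 1.5. Added after the data were seen were the summed level of Y-linked genes as a covariate and GD100 replicate 1 as the only GD100 library. Data were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The labels give no sex, dam, litter or sequencing batch. Their sample codes carry different letters in each stage, and what the letters mean is not known. A cohort, batch or treatment that follows these codes and the stage therefore cannot be told apart.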

Results

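Fetal sheep liver was profiled by poly(A) RNA sequencing at gestational days (GD) 100, 124 and 144, with 4, 5 and 6 libraries, to follow the liver transcriptome through the last part of gestation. Fetal liver holds hepatocytes, which take on metabolic functions towards birth, together with blood-forming cells that leave the organ over the same period. The 15 libraries held 24215612 to 38247295 estimated counts and 18959 to 20109 genes with a count above 0. A count of 3, taken as the floor of detection, corresponded to 0.0784 to 0.124 counts-per-million units (CPM) depending on the library. The 13 protein-coding mitochondrial genes took 3.67 to 13.4% of a library's counts. The 4 genes of the alpha globin cluster took 4.27 to 10.1% of counts at GD100, 1.57 to 3.31% at GD124 and 0.00721 to 0.714% at GD144. GD100 replicates 2 to 4 stood apart in the counting. In them 10.6 to 10.8% of genes carried a fractional count, against 5.09 to 6.2% in the other 12 libraries. The same 3 libraries shared 156 genes that lay over 3 times above every other library at more than 1 CPM. The table does not say whether counting used the strand, so values of genes that overlap another gene in the ARS-UI_Ramb_v3.0 annotation are uncertain. Among the genes named in these results they are AFP, AMY2B, ARMC12, CD34, CDKL3, CFAP119, CPT1A, ELANE, FOXRED2, GP9, GPC3, HNF4A, HSD11B1, IFIT1, IGFBP1, LIN28B, LOC121818276, MEST, P4HA1, PLAGL1, SLC10A1, SLC2A1, SLC37A4, TNNT3, UGT1A3, VTN and YPEL4. Values of UGT1A3, AMY2B and the globin genes are likewise uncertain because near-identical copies can share their reads. For the mitochondrial gene KEF53_p02, matched by locus tag alone, overlap was not looked up. The sample codes in the labels carry different letters in each stage, so a cohort, batch or treatment that follows them and the stage cannot be told apart. Nothing in the labels states that libraries of a stage came from separate fetuses, so p-values measure the spread between these samples.

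Libraries grouped by stage. In the 500 genes with the largest variance, the first principal component held 72.3% of the variance and ordered the stages by gestational day, and the second held 6.7%. The mean correlation distance was 0.612 between stages and 0.203 within a stage. The difference of 0.41 gave a permutation p of 1.0e-05 over 100000 draws, one-sided, which is the smallest that this number of draws can give. For 14 of the 15 libraries the nearest library belonged to the same stage. GD144 replicate 3 lay at 19.38 on the first component, against 55.03 to 76.97 for the other GD144 libraries and -31.77 to -12.57 for GD124. GD100 replicate 1 lay at 21.53 on the second component, against -19.57 to -18.7 for GD100 replicates 2 to 4.

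**Figure D1:**
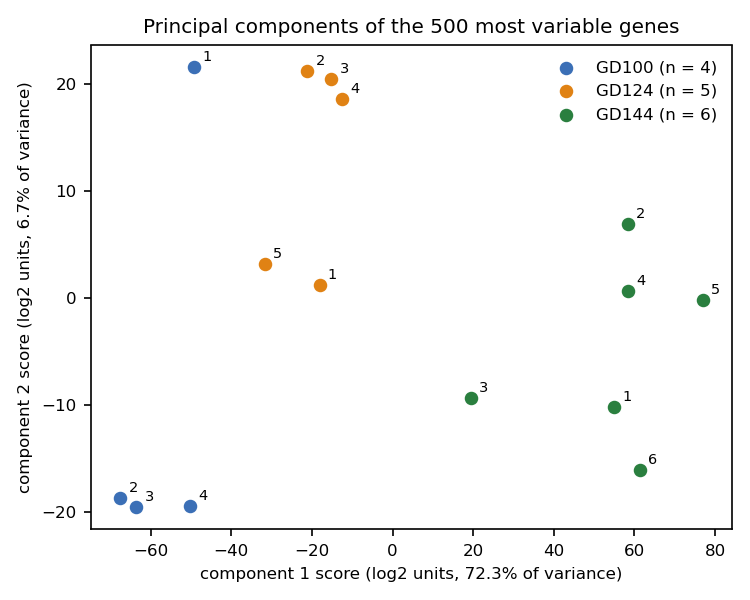
Principal components of log2 CPM in the 500 most variable genes, with 1 point per library coloured by stage and labelled by replicate number; axes are component scores in log2 units. The stages follow one another along the first component (72.3% of variance), with GD144 replicate 3 at 19.38 between GD124 and the other GD144 libraries.

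Between GD100 and GD124 the liver gained transcripts of secreted plasma proteins, of glucose output and of amino acid breakdown, while transcripts of the cell cycle and of several lists of blood-forming cells declined. G6PC1, the catalytic subunit of the enzyme that releases free glucose, rose from 3.35 ± 2.0 CPM (SD, n = 4) to 106 ± 59.1 CPM (SD, n = 5), with a log2 fold change of 4.98 ± 0.53 (SE) and an edgeR adjusted p of 9.17e-05. PCK1, a gluconeogenic enzyme gene, rose from 2.11 ± 1.53 to 32.5 ± 15.1 CPM (log2 3.95 ± 0.65, edgeR adjusted p = 0.00068). AFP, the main plasma protein of the early fetus, fell from 6000.0 ± 2762 to 1467 ± 633 CPM (log2 -2.03 ± 0.46, edgeR adjusted p = 0.0037). ALB, which encodes serum albumin, rose from 27931 ± 16840.4 to 70686 ± 5486 CPM (log2 1.34 ± 0.34, edgeR adjusted p = 0.00647).

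Among secreted proteins, 34 of the 48 tested genes for plasma proteins and coagulation rose and 0 fell (37 and 0 adjusted over the list alone). The fibrinogen chain genes FGG (log2 1.86 ± 0.25) and FGA (log2 1.71 ± 0.26) were among them, as was KNG1, the gene of kininogen (log2 1.48 ± 0.23). The camera adjusted p was 9.49e-17 with the preset correlation, and the adjusted p was 0.269 with an estimated correlation. Of 30 acute phase and complement genes, 20 rose and 0 fell (20 and 0 adjusted over the list alone, camera adjusted p = 5.55e-10, and adjusted p = 0.187 with an estimated correlation). The complement gene C6 rose from 3.78 ± 3.07 to 92.6 ± 40.5 CPM, the lectin gene MBL2 from 27.7 ± 14.2 to 399.7 ± 255 CPM and CRP from 37.4 ± 18.4 to 343 ± 199 CPM. C6, MBL2 and CRP together with G6PC1, PCK1, IGFBP1, AQP9 and UGT1A3 had the 8 largest rises among the genes chosen by the naming rule. IGFBP1, a binding protein of insulin-like growth factors, went from 17.3 ± 16.4 to 285 ± 111 CPM and AQP9, a glycerol channel, from 9.78 ± 2.79 to 83.3 ± 41.4 CPM. UGT1A3, a glucuronidation enzyme, averaged 0.108 CPM at GD100, about the 3-count floor, and 24.6 ± 16.4 CPM at GD124.

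Several groups of metabolic genes moved in the same direction as the plasma proteins. In the list for gluconeogenesis and glycogen 16 of 29 genes rose and 3 fell (17 and 3 adjusted over the list alone), with a camera adjusted p of 6.25e-08 and an adjusted p of 0.152 with an estimated correlation. The glucose transporter gene SLC2A2 rose by log2 2.13 ± 0.25 and GYS2, liver glycogen synthase, by log2 2.45 ± 0.32. For the urea cycle and amino acid breakdown 23 of 47 rose and 1 fell (27 and 1 adjusted over the list alone, camera adjusted p = 3.60e-08, and adjusted p = 0.313 with an estimated correlation). CPS1, which makes the first intermediate of the urea cycle, rose from 1024 ± 377 to 3511 ± 364 CPM, and TAT, a tyrosine-degrading enzyme, rose from 117 ± 37.9 to 323 ± 30.8 CPM. Of the genes for fatty acid oxidation and ketone bodies 17 of 36 rose and 2 fell (18 and 2 adjusted over the list alone, camera adjusted p = 1.04e-05, and adjusted p = 0.336 with an estimated correlation). CPT1A, the mitochondrial fatty acid importer, stood at 43.4 ± 5.49 and 47.8 ± 7.46 CPM (edgeR adjusted p = 0.677). Bile acid genes rose in 12 of 19 cases and fell in 0 (12 and 0 adjusted over the list alone, camera adjusted p = 6.72e-06, and adjusted p = 0.313 with an estimated correlation), with the bile salt importer gene SLC10A1 at log2 2.78 ± 0.39. Drug and steroid metabolism genes rose in 15 of 32 cases and fell in 0 (18 and 0 adjusted over the list alone, camera adjusted p = 7.67e-06, and adjusted p = 0.329 with an estimated correlation). Other metabolic lists did not rise as a whole. Glycolysis genes fell in 7 of 22 cases and rose in 2 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0748), and those of fatty acid and triglyceride synthesis fell in 5 of 28 and rose in 4 (5 and 3 adjusted over the list alone, camera adjusted p = 0.943). With scaling by total counts alone the latter numbers were 8 and 3. Cholesterol synthesis genes fell in 3 of 25 and rose in 2 (3 and 2 adjusted over the list alone, camera adjusted p = 0.924). Periportal genes, those known from the hepatocytes around the portal vein, rose in 14 of 18 cases and fell in 0 (15 and 0 adjusted over the list alone, camera adjusted p = 5.22e-09, and adjusted p = 0.259 with an estimated correlation). Of these 18 genes 13 belong to another list too. Of 18 pericentral genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.937).

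Transcripts of erythroid, platelet and stem cell lists went the other way, and those of granulocytes and myeloid progenitors did not (1 of 15 rose and 1 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.957). In the erythroid list 11 of 30 genes fell and 0 rose (11 and 0 adjusted over the list alone), and the median log2 change was -1.72 (camera adjusted p = 1.46e-05, and adjusted p = 0.512 with an estimated correlation). EPOR, the erythropoietin receptor gene, fell from 79.5 ± 24 to 16.7 ± 5.55 CPM. The erythroid regulator KLF1 (233 ± 87.9 and 60.7 ± 19.1 CPM, edgeR adjusted p = 0.106) and ALAS2 (1119 ± 696 and 295 ± 101 CPM, edgeR adjusted p = 0.113) did not pass the threshold. Proliferation genes fell in 32 of 48 cases and rose in 0 (39 and 0 adjusted over the list alone, camera adjusted p = 1.74e-11, and adjusted p = 0.398 with an estimated correlation). The replication licensing gene MCM2 fell by 1.45 on the log2 scale, while MKI67 (log2 -1.45 ± 0.74, edgeR adjusted p = 0.144) and TOP2A (log2 -1.11 ± 0.49, edgeR adjusted p = 0.0942) did not pass. Megakaryocyte and platelet genes fell in 8 of 15 cases and rose in 0 (10 and 1 adjusted over the list alone, camera adjusted p = 0.000274, and adjusted p = 0.269 with an estimated correlation), with the platelet integrin gene ITGA2B at log2 -2.15 ± 0.30. Stem and progenitor genes fell in 7 of 15 cases and rose in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00149, and adjusted p = 0.259 with an estimated correlation), with CD34 going from 160.1 ± 56.1 to 40.7 ± 13.8 CPM. Kupffer cell and macrophage genes rose instead, in 14 of 21 cases against 1 that fell (16 and 1 adjusted over the list alone, camera adjusted p = 4.11e-07, and adjusted p = 0.324 with an estimated correlation). Libraries of both stages overlapped in the median log2 CPM of this list. It was 2.95 and 3.13 in GD100 replicates 2 and 3, 4.24 and 4.65 in replicates 1 and 4, and 4.35 to 5.46 at GD124. Ribosomal protein genes fell in 40 of 72 cases and rose in 1 (44 and 1 adjusted over the list alone, camera adjusted p = 9.24e-09, and adjusted p = 0.342 with an estimated correlation), by small amounts such as log2 -0.91 ± 0.16 for RPLP0.

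The genes with the 8 largest falls under the naming rule were CDKL3, TREML1, IFIT1, FOXRED2, ISG15, GP9, CFAP119 and TREML2. TREML1 and GP9 are platelet genes, and GP9 fell from 36.1 ± 7.87 to 6.11 ± 1.85 CPM. IFIT1 and ISG15 are interferon-induced genes and ISG15 fell from 156 ± 67.5 to 26.2 ± 9.92 CPM, while 6 of 27 interferon response genes fell and 2 rose (6 and 2 adjusted over the list alone, camera adjusted p = 0.0872). CDKL3 stood at 4.39 CPM in GD100 replicate 1, at 32 to 40.9 CPM in GD100 replicates 2 to 4, and at 3.62 ± 0.485 CPM at GD124. It is one of the genes that set those 3 libraries apart, as are OIP5, SLC22A3 and KEF53_p02, the mitochondrial gene ND6. Overlap was not looked up for KEF53_p02, whose name matched a locus tag alone. Of CDKL3, OIP5 and SLC22A3, CDKL3 alone overlaps another gene in the ARS-UI_Ramb_v3.0 annotation. With GD100 replicate 1 as the only library of that stage its log2 change was -0.28 and it was not called. In the fetal liver and growth list 9 of 24 genes fell and 6 rose (9 and 6 adjusted over the list alone, camera adjusted p = 0.234). PLAGL1, an imprinted growth regulator, fell from 387 ± 109 to 120.4 ± 23.7 CPM and LIN28B from 3.84 ± 1.75 to 0.574 ± 0.281 CPM. GHR, the growth hormone receptor gene, rose from 35.5 ± 13.9 to 101 ± 11.9 CPM and IGF1 from 89.1 ± 28.4 to 196 ± 57.6 CPM. IGF2 (log2 0.70 ± 0.25), GPC3 (log2 0.85 ± 0.29), HSD11B1 (log2 1.19 ± 0.38) and DLK1 (log2 -0.58 ± 0.21) passed the threshold narrowly. In that order their edgeR adjusted p was 0.108, 0.106, 0.0604 and 0.104 without GD100 replicate 2, 0.101, 0.122, 0.0828 and 0.102 without GD100 replicate 3, and 0.0856, 0.0766, 0.0537 and 0.0861 without GD124 replicate 1. At least 1 of them also lost its call without GD100 replicate 1, any of GD124 replicates 2 to 5 or GD144 replicate 2, at adjusted p of 0.052 to 0.0948.

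In all, 5774 of 16977 tested genes differed between GD124 and GD100 at an edgeR adjusted p under 0.05, 2825 higher and 2949 lower at GD124. With GD100 replicate 1 as the only GD100 library, an alternative chosen after the data were seen in which that library is assumed to vary like the others, 3167 genes were called. Most of these genes were called in the same direction with all libraries, very few in the opposite direction, and the rest were not called with all libraries. In that fit AFP, CDKL3, CFAP119, DLK1, EPOR, FBLN5, GP9, HERPUD1, HSD11B1, IFIT1, IGF1, IGF2, ISG15, LBR, LIN28B, MCM2, NR3C1, RGS5, RPLP0, SLC22A3, TREML1 and UGT1A3 were not called. Scaling by total counts alone put the median gene at -0.164 on the log2 scale, where TMM put it at 0.015, and left 1805 higher and 4055 lower calls in this comparison. Random regroupings of the libraries called a median of 49 of the 111 list tests with the preset camera correlation, against 66 with the stages. Statements on lists here therefore describe counts of members, whose changes can be correlated. They are to be read beside the calls over all 16977 tested genes. These were 2825 higher and 2949 lower for GD124 against GD100, 2046 and 2617 for GD144 against GD124, and 4603 and 4739 for GD144 against GD100.

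Between GD124 and GD144 many genes of glucose output, amino acid breakdown, fat oxidation and hormone response rose, while AFP, erythroid genes and genes of the cell cycle fell. AFP fell from 1467 ± 633 CPM (SD, n = 5) to 8.17 ± 5.48 CPM (SD, n = 6), a log2 fold change of -7.49 ± 0.53 (SE, edgeR adjusted p = 3.66e-07). G6PC1 rose to 578 ± 155 CPM (log2 2.45 ± 0.42, edgeR adjusted p = 0.000528) and PCK1 to 151 ± 92.6 CPM (log2 2.21 ± 0.52, edgeR adjusted p = 0.00601). ALB, at 66329.8 ± 10036 CPM, did not differ from GD124 beyond the spread (log2 -0.09 ± 0.29, edgeR adjusted p = 0.852).

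Of 22 genes known to respond to glucocorticoid or thyroid hormone 15 rose and 0 fell (16 and 1 adjusted over the list alone). The camera adjusted p was 1.00e-13, and this call held with an estimated correlation (adjusted p = 0.0177). Between GD100 and GD124 13 of these genes had risen and 2 had fallen (15 and 2 adjusted over the list alone, camera adjusted p = 0.00039, and adjusted p = 0.214 with an estimated correlation). The transcription factor gene ZBTB16 rose from 3.83 ± 1.17 to 69.4 ± 18.4 CPM, KLF9 from 11.3 ± 3.61 to 100.0 ± 17.3 CPM, and the clock gene PER1 from 13.9 ± 3.57 to 57.1 ± 5.25 CPM. HSD11B1, whose enzyme regenerates active glucocorticoid, rose from 89.7 ± 29.5 to 539 ± 140.4 CPM (log2 2.59 ± 0.37), and NR3C1, the glucocorticoid receptor gene, from 69.3 ± 8.89 to 98 ± 6.44 CPM. Over the same interval 10 of 30 immediate early and heat shock genes rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.000396, and adjusted p = 0.313 with an estimated correlation). DUSP1, which both lists hold, rose from 50.3 ± 16.8 to 229 ± 63.7 CPM and MYC from 14.2 ± 2.06 to 64.9 ± 23.8 CPM.

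For gluconeogenesis and glycogen 19 of 29 genes rose and 2 fell (22 and 3 adjusted over the list alone, camera adjusted p = 1.23e-09, and adjusted p = 0.121 with an estimated correlation). SLC37A4, the glucose-6-phosphate transporter gene, rose from 38 ± 6.79 to 315 ± 80.5 CPM and PPP1R3C, a glycogen-targeting phosphatase subunit gene, from 60.7 ± 20.5 to 243 ± 21.4 CPM. Urea cycle and amino acid genes rose in 23 of 47 cases and fell in 1 (25 and 1 adjusted over the list alone, camera adjusted p = 9.41e-09, and adjusted p = 0.313 with an estimated correlation). ASL, a urea cycle enzyme gene, rose from 293 ± 48.7 to 874 ± 179 CPM and GNMT, a glycine methyltransferase gene, from 9.42 ± 1.51 to 139.7 ± 102 CPM. CPS1 reached 6055 ± 2015 CPM (log2 0.79 ± 0.27, edgeR adjusted p = 0.0376), a call lost without any 1 of GD124 replicates 1, 2, 4 and 5 and GD144 replicates 3 to 6 (edgeR adjusted p of 0.0568 to 0.0821). Fatty acid oxidation and ketone body genes rose in 23 of 36 cases and fell in 1 (24 and 3 adjusted over the list alone, camera adjusted p = 1.29e-08, and adjusted p = 0.269 with an estimated correlation). CPT1A rose from 47.8 ± 7.46 to 156 ± 65.4 CPM and PDK4, a kinase that restrains pyruvate oxidation, from 28.5 ± 5.28 to 211 ± 119.8 CPM. Plasma protein genes, in contrast, rose in 7 of 48 cases and fell in 2 (4 and 2 adjusted over the list alone, camera adjusted p = 0.324). With scaling by total counts alone 11 of them rose. Acute phase and complement genes rose in 11 of 30 cases and fell in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 9.28e-06, and adjusted p = 0.299 with an estimated correlation). The largest rises under the naming rule were those of SDS, ARMC12, XDH, LPIN1, GK, CYP2E1, SDSL and CES4A. SDS, serine dehydratase, went from 3.02 ± 1.01 to 149 ± 177 CPM, LPIN1, a phosphatidate phosphatase gene, from 7.76 ± 3.43 to 227 ± 200.1 CPM, and CYP2E1, an ethanol- and drug-oxidising cytochrome, from 2.69 ± 2.2 to 50.6 ± 42.3 CPM. Their spread between GD144 libraries was wide, as the standard deviations show. SLC10A1 rose again, from 131 ± 16.6 to 768 ± 78.3 CPM, within 9 of 19 bile acid genes that rose and 0 that fell (9 and 0 adjusted over the list alone, camera adjusted p = 2.77e-05, and adjusted p = 0.342 with an estimated correlation).

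**Figure D2:**
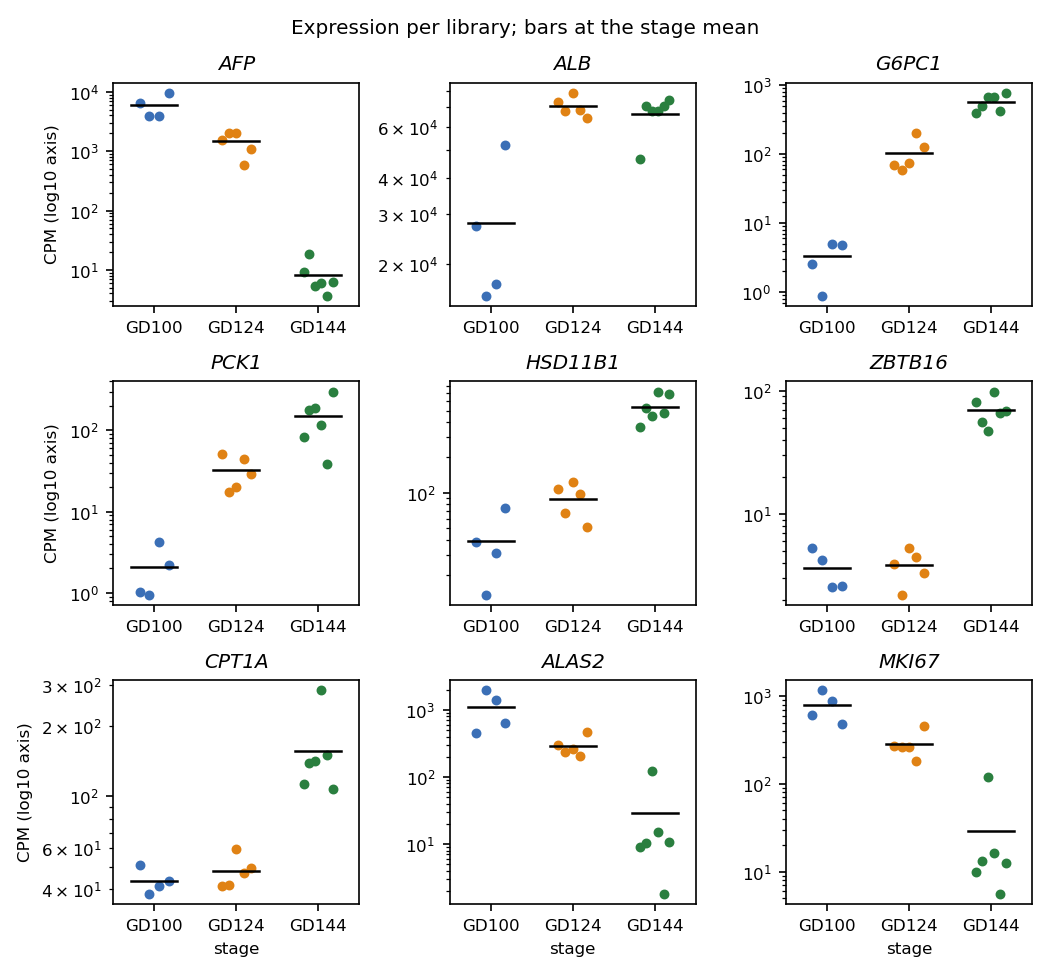
TMM-normalised CPM on a log10 axis for 9 named genes, with 1 point per library (4 at GD100, 5 at GD124, 6 at GD144) and a bar at the stage mean. AFP went from a mean of 6000.0 CPM at GD100 to 8.17 CPM at GD144, and G6PC1 from 3.35 to 578 CPM.

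Erythroid genes fell in 28 of 30 cases and rose in 0 (28 and 0 adjusted over the list alone), with a median log2 change of -3.38 (camera adjusted p = 8.71e-19, and adjusted p = 0.269 with an estimated correlation). KLF1 fell from 60.7 ± 19.1 to 4.64 ± 8.27 CPM and ALAS2, the erythroid gene for the first enzyme of haem synthesis, from 295 ± 101 to 28.6 ± 47 CPM. Proliferation genes fell in 47 of 48 cases and rose in 0 (48 and 0 adjusted over the list alone, camera adjusted p = 6.30e-42, and adjusted p = 0.218 with an estimated correlation), MKI67 from 288 ± 101 to 29.3 ± 43.8 CPM and TOP2A from 73.1 ± 18.5 to 10.4 ± 9.46 CPM. Megakaryocyte and platelet genes fell in 10 of 15 cases and rose in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 0.00791, and adjusted p = 0.351 with an estimated correlation). Stem and progenitor genes fell in 7 of 15 cases and rose in 3 (8 and 3 adjusted over the list alone, camera adjusted p = 0.0378, and adjusted p = 0.342 with an estimated correlation). That call was lost without GD124 replicate 2 (adjusted p = 0.0503) or GD144 replicate 2 (0.0526) and with GD100 replicate 1 as the only GD100 library (0.0909). GD144 replicate 3 kept more of the erythroid and proliferation transcripts, with 124 CPM of ALAS2 and 118 CPM of MKI67, and its alpha globin share of 0.714% was the highest of that stage. Genes of the sinusoidal and vascular endothelium rose in 17 of 22 cases and fell in 0 (20 and 0 adjusted over the list alone, camera adjusted p = 3.60e-08, and adjusted p = 0.295 with an estimated correlation), with the receptor gene FLT1 at log2 1.46 ± 0.28. Stellate cell and matrix genes rose in 13 of 32 cases and fell in 0 (13 and 0 adjusted over the list alone, camera adjusted p = 6.10e-06, and adjusted p = 0.324 with an estimated correlation), with the elastic fibre gene FBLN5 at log2 1.24 ± 0.17.

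Fetal liver and growth genes fell in 11 of 24 cases and rose in 1 (11 and 1 adjusted over the list alone), a call that held with an estimated correlation (camera adjusted p = 1.73e-08 with the preset and adjusted p = 0.0191 with the estimated correlation). PLAGL1 fell from 120.4 ± 23.7 to 6.87 ± 1.25 CPM (log2 -4.13 ± 0.20), the imprinted gene MEST from 431 ± 99.4 to 119 ± 33 CPM and DLK1 from 406 ± 48 to 183 ± 55 CPM. IGF2 was at 8091 ± 1142 and 9873 ± 2447 CPM (edgeR adjusted p = 0.365) and GPC3 at 1927 ± 292 and 1935 ± 266 CPM (edgeR adjusted p = 0.992), differences within the spread. Among the largest falls under the naming rule were those of AFP, OSM, TOX3, YPEL4, SLC38A5, ICAM5 and PLAGL1. OSM, a cytokine gene, went from 11 ± 1.21 CPM to 0.129 CPM, close to the 3-count floor.

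Between these stages 4663 genes differed at an edgeR adjusted p under 0.05, 2046 higher and 2617 lower at GD144. With scaling by total counts alone, 2520 were higher and 2138 lower.

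Across the whole span from GD100 to GD144, 9342 genes differed, 4603 higher and 4739 lower at GD144, and 9554 of the 16977 tested genes differed between any of the stages. AFP fell by 9.52 on the log2 scale (SE 0.58, edgeR adjusted p = 1.36e-08) and G6PC1 rose by log2 7.43 ± 0.59 (edgeR adjusted p = 1.46e-07). Also among the 8 largest rises of the naming rule were UGT1A3, PCK1, SDS, SDSL and LPIN1, together with RGS5, a pericyte gene (0.327 ± 0.278 to 54.3 ± 26.2 CPM), and AMY2B, an amylase gene (0.644 ± 0.392 to 57.8 ± 49.4 CPM). UGT1A3 ran from 1.25 to 298.9 CPM between GD144 libraries. Its 1.51 and 1.25 CPM in GD144 replicates 1 and 2 lay below the 5.89 to 49.4 CPM of GD124. The falls included KCNN4, OSM, GP9, YPEL4, PKMYT1, OIP5 and ACHE besides AFP. ACHE, which encodes acetylcholinesterase, an enzyme also found on red cells, went from 110.3 ± 27.2 to 1.57 ± 2.72 CPM, and PKMYT1, a mitotic kinase gene, from 13 ± 5.07 to 0.154 ± 0.16 CPM. SLC2A1, a glucose transporter gene, fell from 724 ± 257 to 18.7 ± 2.94 CPM within a glycolysis list of which 9 of 22 genes fell and 8 rose (9 and 8 adjusted over the list alone, camera adjusted p = 0.462). Hepatocyte transcription factor genes rose in 25 of 30 cases and fell in 2 (25 and 2 adjusted over the list alone, camera adjusted p = 6.54e-06, and adjusted p = 0.299 with an estimated correlation), HNF4A from 114 ± 23.1 to 324 ± 44.5 CPM. For glucocorticoid and thyroid hormone response 18 of 22 genes rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 3.35e-10, a call that held at adjusted p = 0.0297 with an estimated correlation). CYP2E1 averaged 2.72 ± 1.2 CPM at GD100, and HAMP, the hepcidin gene, rose from 2.96 ± 2.62 to 10.4 ± 5.28 CPM (log2 1.82 ± 0.54, edgeR adjusted p = 0.00994). With GD100 replicate 1 as the only GD100 library, CYP2E1, HAMP, IFIT1, ISG15, KEF53_p02, SDS, SDSL and UGT1A3 were not called in this comparison.

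**Figure D3:**
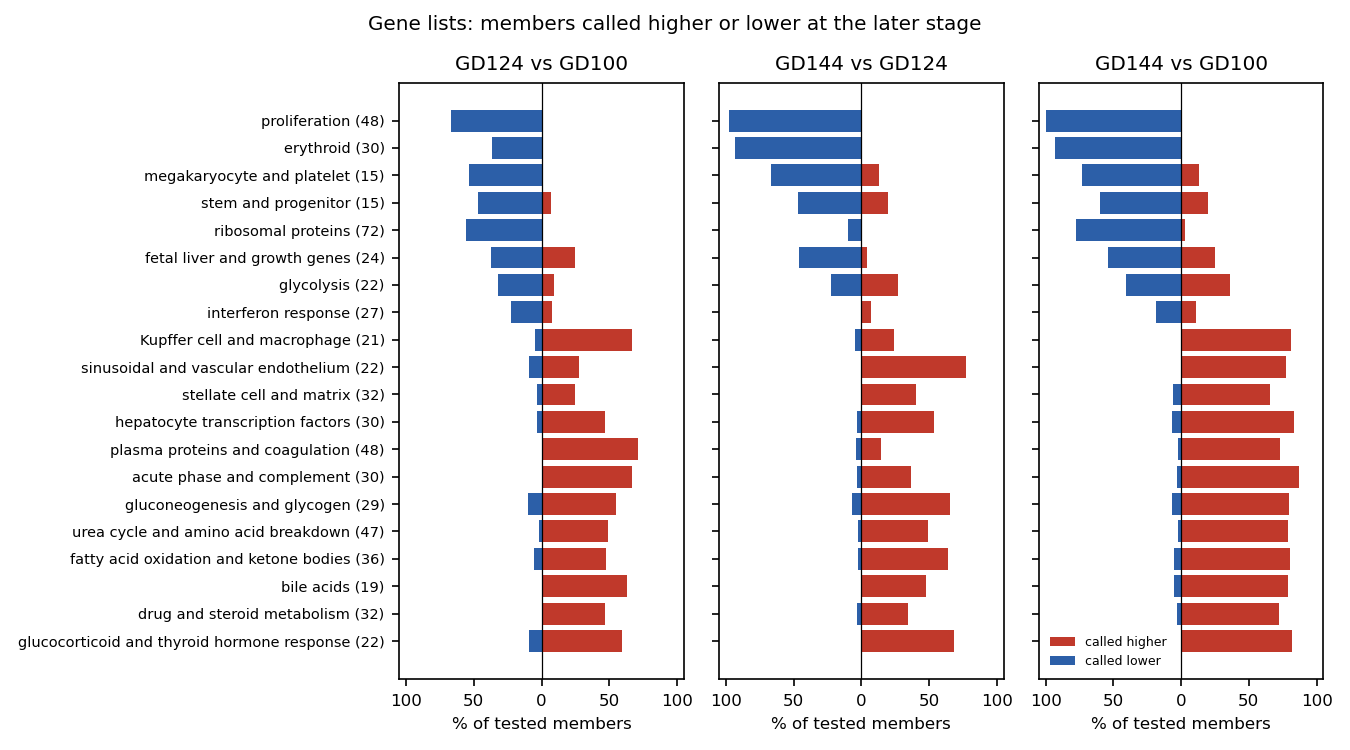
Share of tested members of 20 gene lists called higher (bars to the right) or lower (bars to the left) at the later stage in each pairwise comparison, in percent, with the number of tested members beside each list name. Proliferation and erythroid genes were called lower in 47 of 48 and 28 of 30 cases between GD124 and GD144, and 23 of 47 urea cycle and amino acid genes were called higher.

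The course over both intervals was read from the same fit. A total of 680 genes rose in both intervals and 1174 fell in both, whereas 192 rose then fell and 101 fell then rose. AFP, PLAGL1 and OSM were among those that fell in both, and G6PC1, PCK1 and SLC10A1 among those that rose in both. The intervals share the GD124 libraries. Simulated tables without any stage effect gave a mean of 0 genes in each of these patterns. With no stage effect few genes can pass the threshold even once, so this 0 cannot show how much overlap the shared libraries cause. In these tables the log2 changes of both intervals had a correlation of -0.495 across genes. Independent lists of the same sizes would give 340.5 genes higher in both, 454.6 lower in both, 435.5 higher then lower and 355.4 lower then higher. With GD124 replicates 1 and 2 used for the earlier interval and 3 to 5 for the later one, the numbers were 383, 674, 65 and 18. The observed correlation across genes, which are not independent replicates, was 0.32 with a covariance of 0.299, against -0.0757 in the simulated tables.

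The test of the difference between both changes called 1002 genes, 365 with a more positive and 637 with a more negative change over the later interval. MYC fell over the earlier interval (log2 -0.96 ± 0.31) and rose over the later one (log2 2.19 ± 0.30), and PCK2, the mitochondrial counterpart of PCK1, did likewise (log2 -0.67 ± 0.23 and 1.86 ± 0.22). CCND1, a cyclin gene, rose (log2 2.11 ± 0.30) and then fell (log2 -1.05 ± 0.25), as did SLC40A1, the iron exporter gene (log2 0.81 ± 0.18 and -0.66 ± 0.16). MBL2 changed by log2 3.85 ± 0.52 over the earlier and -0.02 ± 0.40 over the later interval, and ZBTB16 by 0.07 ± 0.28 and 4.17 ± 0.28, with an edgeR adjusted p of the difference of 0.00887 and 0.0005. AFP fell further over the later interval than over the earlier one (edgeR adjusted p of the difference = 0.00132). For ALB, called over the earlier interval alone, the changes did not differ beyond the spread (edgeR adjusted p of the difference = 0.113). This count of 1002 moved with single libraries, from 379 without GD124 replicate 2 to 1743 without GD100 replicate 4. It was 628 without GD100 replicate 2, 515 without GD100 replicate 3, 501 without GD124 replicate 1, 629 without GD124 replicate 3 and 482 without GD124 replicate 4. Scaling by total counts alone put the median gene at 0.217 in this contrast, where TMM put it at -0.0424, and turned the split of 365 and 637 to 789 and 388. The DESeq2 test called 1793 genes.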

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

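The tests of neighbour genes, fetal sex, the stage of GD100 replicate 1, blood-forming cells, VTN and the metabolic score of GD144 replicate 3 were chosen only after the result was seen. Of 312 sets formed by a named gene or library measure within 1 stage, 31 held a library whose gap to its nearest neighbour took a larger share of the whole range than Dixon's 95% critical value allows. Chance flags about 1 in 20 groups. GD144 replicate 3 accounted for 14 of these sets and GD100 replicate 1 for 5.

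In GD144 replicate 3, several named genes lay above the 5 other GD144 libraries, among them KLF1 of the erythroid list and MKI67 and TOP2A of the proliferation list. The gap as a share of the range was 0.896 for the alpha globin share, 0.836 for ICAM5, 0.801 for ACHE, 0.761 for LBR, 0.748 for OIP5, 0.685 for TOP2A, 0.676 for LIN28B, 0.657 for MKI67, 0.647 for CFAP119, 0.64 for SLC38A5, 0.633 for YPEL4 and 0.632 for KLF1. MKI67 stood at 118 CPM there against 5.56 to 16.3 CPM in the others and KLF1 at 21.5 against 0.15 to 1.87 CPM. The alpha globin share was 0.714% of counts against 0.00721 to 0.0805%. In the same library the secreted proteins VTN and ORM1, both picked after their values were seen, lay low, VTN at 276 CPM against 5905 to 7256 CPM and ORM1 at 3.29 against 469 to 1310.5 CPM, with a gap of 0.937 for VTN and 0.824 for ORM1. ORM1 averaged 5.0 CPM at GD124, near its level in this library, whereas VTN was at 1132 CPM or more in each of the other 14 libraries.

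A GD124 sample under the GD144 label is argued against as the explanation for this library, because its metabolic score of 7.27 lay far from the 6.1 to 6.42 of GD124 and within the 6.65 to 7.37 of the other GD144 libraries. AFP stood at 5.36 CPM in it against 595 to 2057 CPM at GD124, PLAGL1 at 8.52 against 102 to 160.3 CPM and ZBTB16 at 47 against 2.2 to 5.27 CPM. Of 4450 genes called between GD144 and GD124 without this library, 72.2% lay nearer to the other GD144 libraries, between the bounds of 50 and 80% set for an earlier stage, against 84.9 to 95.0% in each of the others, with which those genes were called. A stage between GD124 and GD144 and a fetus of GD144 that kept more blood-forming cells therefore cannot be told apart, and a difference in maturity between fetuses was not tested. A larger share of blood-forming cells (erythroid score 5.36 against -0.585 to 2.52) is argued against as the cause of the low VTN, at -4.52 on the log2 scale from the mean of the others, since the other 47 plasma protein genes had a median change of 0.0578 (SD 0.274, from -0.522 to 0.794).

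GD100 replicate 1 lay below the other 3 libraries of its stage with a gap of 0.952 for the share of fractional counts, 0.951 for OIP5 and 0.888 for CDKL3, and above them with a gap of 0.889 for the total count and 0.859 for TNNT3. CDKL3 stood at 4.39 CPM in it against 32 to 40.9 CPM, and OIP5 at 5.18 against 45.9 to 51.2 CPM. The contrast belongs to a wider one, in which GD100 replicates 2 to 4 shared 156 genes, 88 of them long non-coding, that lay over 3 times above every other library. None of the 454 other sets of 3 libraries shared more than 4 such genes.

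Reads of an overlapping neighbour gene, counted in these 3 libraries and not elsewhere, are a candidate explanation for that set. Of its genes with a position 78.7% (122 of 155) overlap another gene, against 40.9% (6664 of 16282) of other expressed genes (Fisher's exact test p = 1.91e-21, over genes that are not independent), with 84.1 against 53.4% for long non-coding and 71.6 against 39.7% for protein-coding genes. Sex of the fetuses on its own is argued against. The 5 later libraries with little Y-linked expression had fractional counts in at most 6.1% of genes. That lay under the 10.6 to 10.8% of GD100 replicates 2 to 4, which were picked by this share. Within GD100 the contrast followed Y-linked expression, at 184.2 CPM in replicate 1 and at most 0.0405 CPM in replicates 2 to 4. An effect of sex at that stage is therefore not argued against. The stage stays open, because the 6.05% of GD100 replicate 1 comes from a single library. Between GD100 and GD124 91 of the 92 tested genes of the set were called lower, so those calls and a difference in counting cannot be told apart.

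Liver genes rose while erythroid transcripts fell (1 of the 30 erythroid and 4 of the 48 plasma protein genes belong to another list too), and a smaller share of blood-forming cells could raise all other genes alike. Over the later interval that explanation is argued against as the whole cause, since metabolic genes rose by a median score of 0.884 while plasma protein genes moved by -0.167 (exact permutation p = 0.00433 for the difference of 1.05, two-sided, adjusted p = 0.0179 over 15 such exact tests). Vessel and stellate genes rose by 0.745, which did not differ from the metabolic genes beyond the spread (difference 0.139, adjusted p = 0.485), so a part played by the smaller share is not excluded. Over the earlier interval the plasma protein score rose by 0.908 more than that of vessel and stellate genes (exact permutation p = 0.0317, two-sided, adjusted p = 0.0679). These scores therefore cannot tell a smaller share and a change within hepatocytes apart over that interval. Of 18 periportal genes 14 rose and 0 fell there, and of 18 pericentral genes 1 rose and 2 fell, a contrast that was not tested. The maturation of hepatocytes with gestational day stays open as the biological explanation.

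Single libraries stood apart in other genes too. In GD124 replicate 5 ACHE and YPEL4, both also high in GD144 replicate 3, and the alpha globin share lay above the other GD124 libraries, with 0.915 for YPEL4, 0.869 for the alpha globin share and 0.717 for ACHE. In GD100 replicate 4 PPP1R3C was low at 22.8 CPM against 31.4 to 32.7 CPM in the rest (gap 0.889). In GD124 replicate 1 MYC was high at 17.8 CPM against 12.5 to 13.7 CPM in the rest (gap 0.746) and SQLE was high at 60.8 CPM against 35.6 to 39.4 CPM in the rest (gap 0.815). In GD124 replicate 2 CES4A was low at 3.06 CPM against 9.26 to 11.1 CPM in the rest (gap 0.856). In GD144 replicate 1 ALB was low at 46350.0 CPM against 67790.0 to 73950.0 CPM in the rest (gap 0.814) and SLC10A1 was low at 619.8 CPM against 749.5 to 828 CPM in the rest (gap 0.655). In GD144 replicate 2 GHR was low at 148 CPM against 172 to 188 CPM in the rest (gap 0.64) and MYC was low at 19.5 CPM against 60.8 to 84.8 CPM in the rest (gap 0.773). In GD144 replicate 4 CPT1A was high at 285 CPM against 108 to 151 CPM in the rest (gap 0.65).

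The change differed between both intervals for 1002 genes. CCND1 and SLC40A1 rose and then fell, with differences of -3.16 and -1.47 between the later and the earlier log2 change, and so did SEL1L with -1.63. MYC fell and then rose, with a difference of 3.15, as did PCK2 with 2.53.

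Regrouped libraries show whether chance alone could give as many calls. For GD124 against GD100 with only those stages, the real grouping was the 1 of 100 splits with as many calls. It gave 5160 against 2707 in the highest other, which argues against chance. That other split differed from the real one in placing 1 GD124 library, replicate 5, with GD100, which points to a structure of the samples. For GD144 against GD124 the real grouping was 1 of 100 as well (5262 against 10), and for GD144 against GD100 1 of 100 (8695 against 949). For any stage it was 1 of 60 (9554 against 148), and each of these argues against chance. Shares of 1 of 100 and 1 of 60 are the smallest that these numbers of splits can give, so chance is not excluded. For the difference between intervals the real grouping was 1 of 60 (1002 against 37). These regroupings mix all stages, so they test for no stage effect and not for equal changes over both intervals. They therefore cannot exclude chance for that count. For the gene lists with the preset correlation chance is not excluded, since 5 of 60 splits gave as many list calls as the 66 of the stages, with 70 in the highest other.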

How the results depend on the processing

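The fits with GD100 replicate 1 as the only GD100 library and with the summed level of Y-linked genes as a covariate were chosen after the data were seen. The naming rule gave 464 results of a gene in a pairwise comparison, 448 of them called, and 307 of these calls held in the same direction under every alternative run on them, leave-one-out included. Of the 16 results that were not called, 10 stayed so throughout, and none of the 464 changed direction as a call. Scaling by total counts alone ended 12 of the calls, no filter 11, the Y-linked covariate 10, and leaving out 1 library 2 to 17. The fit with GD100 replicate 1 alone gave such results only for comparisons with GD100. The test against a fold of 1.5 ended 104 of the calls, GD100 replicate 1 alone ended 70, limma-voom 9, RLE size factors 3 and DESeq2 1.

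With the exceptions given here, the counts of genes that differed between the stages stayed within 1.5 times of those reported under the scalings, filters and tests run. For GD124 against GD100 the count of 5774 ranged from 4169 to 6234 with 1 library left out, for GD144 against GD124 the count of 4663 from 3724 to 5051, for GD144 against GD100 the count of 9342 from 8546 to 9321, and for any stage the count of 9554 from 8589 to 9693. A test against a fold of 1.5 with glmTreat asks for more than a change, and it left 1315, 1641 and 5363 genes in the pairwise comparisons in that order. With GD100 replicate 1 alone, 3167 genes were called between GD100 and GD124, and 7182 between GD100 and GD144, in a fit with fewer libraries. The Y-linked covariate left 5110, 4656 and 9048 genes in the pairwise comparisons.

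The difference between both intervals was the least stable count. It was 1002 genes, 1793 with DESeq2 (875 more positive and 918 more negative changes over the later interval), 848 with GD100 replicate 1 alone and 849 with the Y-linked covariate. With 1 library left out it ran from 379 without GD124 replicate 2 to 1743 without GD100 replicate 4, and it was 628 without GD100 replicate 2, 515 without GD100 replicate 3, 501 without GD124 replicate 1, 629 without GD124 replicate 3 and 482 without GD124 replicate 4. Apart from the smaller number of libraries, the cause was not tested.

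The replicate number as a block gave 4544, 3306 and 8259 genes in the pairwise comparisons, 7977 for any stage and 325 for the difference between intervals. The fit then has fewer residual degrees of freedom, 7 in place of 12. The 13 pairs of libraries with the same number had correlations of -0.155 to 0.144 in their deviations from the stage means, with a mean of -0.0367 against 0.0077 for other pairs, and 2 libraries correlated best with their own number, so the numbers do not pair the samples. The block changed the call of 1 of the 111 list tests and of 20 results of named genes.

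Of the 66 list calls with the preset correlation 3 held with an estimated correlation. The fry test called 75 of all list tests, ending 3 of the 66 calls and adding 12 others. With 1 library left out, 65 to 69 of all list tests were called. The 13 genes of the mitochondrial genome changed direction between GD100 and GD124, from 0.0408 to -3.1 as the signed negative log10 of the camera p, with GD100 replicate 1 alone (camera adjusted p = 0.00174, against 0.943 with all libraries). That library had the highest mitochondrial share of all, 13.4% of counts, so this call rests on 1 library. The same fit ended 3 list calls, those of bile duct and unfolded protein response genes between GD100 and GD124 and of stem and progenitor genes between GD124 and GD144. The distance between stages exceeded that within stages by 0.41 in correlation distance, by 0.245 over 2000 genes and by 0.425 without the erythroid and proliferation lists.

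Thinning every library to the smallest total left 5699, 4588 and 9193 calls in the pairwise comparisons, close to the full counts, whereas genes below the 3-count floor of 0.0784 to 0.124 CPM were not detectable.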

Other observations

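The lists and comparisons described here were fixed beforehand, while the per-library values of LOC121818276 and of the Y-linked genes, the Y-linked covariate and the fit with GD100 replicate 1 alone were chosen after the data were seen. Several gene groups outside the main account moved between the stages. Between GD100 and GD124 12 of 25 genes of the unfolded protein response rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.00085, and adjusted p = 0.474 with an estimated correlation), among them SEL1L (log2 1.08 ± 0.20) and HERPUD1 (log2 1.02 ± 0.21), both of protein degradation at the endoplasmic reticulum. In the growth hormone and IGF axis 10 of 21 genes rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0088, and adjusted p = 0.269 with an estimated correlation), including IGFBP4 from 510.4 ± 142 to 1019 ± 94.6 CPM. Of 23 hypoxia genes 6 rose and 6 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.472), and P4HA1, a collagen-modifying enzyme gene, went from 8.43 ± 1.68 to 39.4 ± 9.87 CPM. Between GD124 and GD144 9 of 25 cholesterol synthesis genes fell and 0 rose (10 and 0 adjusted over the list alone, camera adjusted p = 0.0305, and adjusted p = 0.612 with an estimated correlation), a camera call lost without GD124 replicate 1 (adjusted p = 0.176). SQLE, a sterol pathway epoxidase gene, fell from 41.6 ± 10.8 to 13.9 ± 1.93 CPM and LBR, which also belongs to the nuclear envelope, from 104 ± 29.6 to 22.7 ± 13.2 CPM. Of 15 granulocyte and myeloid progenitor genes 6 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 0.00085, and adjusted p = 0.447 with an estimated correlation), ELANE, a neutrophil protease gene, from 3.83 ± 1.91 to 0.976 ± 0.664 CPM. Over the whole span 8 of 28 genes of fatty acid and triglyceride synthesis rose and 6 fell (7 and 6 adjusted over the list alone, camera adjusted p = 0.721). Of all 16977 tested genes 4603 rose and 4739 fell over this span, so the share of rises in this list was near that of all genes. With scaling by total counts alone 7 genes of the unfolded protein response rose and 2 fell, and 5 hypoxia genes rose and 7 fell. Of the granulocyte and myeloid progenitor genes 3 fell, and 6 genes of fatty acid and triglyceride synthesis rose and 8 fell.

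Other lists stood for cells that a piece of liver can hold and for further functions. Bile duct genes rose between GD100 and GD124 in 5 of 20 cases and fell in 1 (5 and 0 adjusted over the list alone, camera adjusted p = 0.0408, and adjusted p = 0.577 with an estimated correlation). Over the whole span 8 of them rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.127). The earlier bile duct call was lost with the Y-linked covariate (adjusted p = 0.0624), with GD100 replicate 1 as the only GD100 library (0.194) and without GD100 replicate 2 (adjusted p = 0.0874), GD100 replicate 3 (0.11), GD124 replicate 3 (0.0789) or GD124 replicate 4 (0.0719). MHC class II genes rose over this interval in 4 of 9 cases and fell in 0 (5 and 1 adjusted over the list alone, camera adjusted p = 0.0606), with OVAR-DRB1 at 14.9 ± 3.17 and 32 ± 4.92 CPM. From GD100 to GD144 lymphocyte genes rose in 3 of 17 cases and fell in 3 (2 and 3 adjusted over the list alone, camera adjusted p = 0.798). Mesothelial genes rose in 1 of 7 cases and fell in 2 (1 and 2 adjusted over the list alone, camera adjusted p = 0.746), with a positive median of 0.90 beside a camera direction downwards, and MSLN fell from 5.65 ± 1.46 to 0.617 ± 0.604 CPM. For muscle, adrenal and pancreas 0 of 7 genes rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.55), and TNNT3, a muscle troponin gene, fell from 5.4 ± 0.766 to 0.276 ± 0.0897 CPM. Between GD124 and GD144 2 of 21 iron handling genes rose and 6 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.304). ERFE, the gene of the erythroid hormone erythroferrone, fell from 18.8 ± 5.48 to 1.58 ± 0.896 CPM. Nuclear genes of oxidative phosphorylation rose in 6 of 43 cases and fell in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 0.00474, and adjusted p = 0.68 with an estimated correlation). With scaling by total counts alone 10 of these rose, and with the fry test the list was not called (adjusted p = 0.121). With the main scaling 2046 of all 16977 tested genes rose over this interval, a share near that of this list. Of the 13 mitochondrial genes 0 rose and 1 fell between GD100 and GD124 (0 and 1 adjusted over the list alone, camera adjusted p = 0.943). The gene that fell was KEF53_p02, ND6 of the mitochondrial genome, at 45.2, 67.7 and 119 CPM in GD100 replicates 2 to 4, 9.38 CPM in GD100 replicate 1 and 0.792 to 4.95 CPM in the 11 later libraries.

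LOC121818276 spread widely within every stage. It stood at 21148, 5053, 1987 and 8798 CPM in GD100 replicates 1 to 4, at 269, 10020.0, 155, 12277 and 156 CPM in GD124 replicates 1 to 5, and at 5245, 8442, 366, 226, 137 and 225 CPM in GD144 replicates 1 to 6. The summed level of Y-linked genes was 184.2 CPM in GD100 replicate 1, 133, 117.8 and 140.8 CPM in GD124 replicates 2 to 4, and 145.3, 135.2 and 142.6 CPM in GD144 replicates 2, 4 and 5, with at most 0.527 CPM in the other libraries.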
